A study of Mus musculus with 6 samples.

How the data were processed

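Cerebral cortex RNA from mice aged 12 months was profiled in 3 WT libraries and 3 libraries labelled Fam69c knockout. Per the labels' protocols, RNA was extracted with Trizol and libraries were built with an Illumina TruSeq RNA kit. The submitters' processing notes name Bowtie, with no version, and the mm10 genome build. The counting program, its handling of strand and of reads with several matches, and the annotation release are not given in the sources used here. Replicates were not pooled.

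The authors deposited 1 table of FPKM values for 54532 genes with gene name, position, strand, length and type. In each library 100% of the values above 0, multiplied by gene length, were whole multiples of 1 step within 0.001, which gave the reads behind each value: 31612849, 30935326 and 32707769 reads in WT and 34112858, 33068481 and 35065884 reads in the libraries labelled knockout. The deposited FPKM carry a further factor per library, since values times length sum to between 0.979 and 1.01 of the total that plain FPKM would give. Of the rows, 98.3% have the same start and end as GENCODE release M21, which was used for exon overlaps and transcript sequences.

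The remaining steps were computed here from the deposited FPKM values. The design called for a count test only if the table held counts, and it held none, so limma 3.58.1 in R 4.3.3 was used. Genes with a mean of at least 0.5 FPKM entered, 15694 in all, of which 12987 code for protein and 486 have models under 200 bases. Values were taken as log2(FPKM + 0.5), so fold changes are on that scale and understate the change of low genes. A linear model with a variance trend compared the groups without a block or covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values with ± are mean and SD over 3 libraries.

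For the 39 gene lists, camera was run with a preset correlation of 0.01, and camera with an estimated correlation and fry beside it, adjusted over the lists. Members were also adjusted over the list alone. Lists overlap in a few genes, and several cell type lists hold genes that other cells of the cortex express too. List means per library were compared by a two-sided exact permutation test. Lists with fewer than 3 measured members were not tested.

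Genes were named by a rule set before the data were examined. Fam69c came first, then genes past the threshold with groups that do not overlap, or, with fewer than 3 past it in a direction, the 6 with the smallest p in that direction. From each list up to 4 members with the smallest p could be named, and 9 genes of the inflammasome and of stress granules in any case. Rps27, D030046N08Rik, Gm47283, Lcn2, Ccl6, Tnf, Il6, Cx3cr1, Slc17a7, Drd2, Lrrc10b, Gapdh and Ccl21b fall outside this rule and were chosen after their values were seen.

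On simulated data with 200 genes changed among 15694 in each of 10 draws, the test recovered 82.5% of genes changed by 2-fold and 95.9% of those changed by 4-fold, with 9.9 false calls among 188.3. With 20 genes changed it recovered 64.0% and 84.0%. Changes of 2-fold and 4-fold were simulated on FPKM + 0.5, so in low genes they stand for larger changes of FPKM itself. A list of 25 genes shifted by 0.5 log2 units was found, at an unadjusted camera p under 0.05, in 10 of 10 draws, and an unshifted list in 1 and 0 of 10 draws. Simulated genes were drawn independently, while members of measured lists moved together, with an estimated correlation of 0.79 for ribosomal protein genes. The draws therefore do not show how often camera with a preset correlation calls such lists, and the gene recovery holds for independent genes.

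Alternatives set beforehand were other pseudocounts, filters, scalings, variance settings, sample weights, thresholds, a block by replicate number and leaving out each library. Others were chosen after the data were seen: voom on the recovered reads, the striatum list as a covariate, leaving out 2 libraries low in striatum genes together, models of 200 bases or longer, and removal of a gene length trend. No pair of libraries agreed within sampling noise, the closest having a median chi-square, over 18245 genes, of 2.86 times that of sampling noise alone. Sequences were aligned with Biopython 1.88 and plots drawn with matplotlib 3.10.9.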

Results

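RNA was sequenced from the cerebral cortex of mice aged 12 months, in 3 wild-type (WT) libraries and 3 libraries labelled as knockout of Fam69c. Fam69c, also called Dipk1c, belongs to a small family of kinase-like proteins of the secretory pathway. The title of the series names stress granule assembly, the gathering of stalled messenger RNA and its binding proteins, and inflammasome activation, the caspase-1 pathway that matures interleukins. The table held FPKM values for 54532 genes in 6 libraries, from 30935326 to 35065884 reads per library as recovered from the values. Genes above 0 numbered from 25630 to 26586 per library. The labels do not say that each library came from a separate mouse, so the tests measure the spread between libraries.

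The targeted gene was measured first, since its RNA can check the labels. Fam69c (ENSMUSG00000047992, mm10 chromosome 18, 84720019 to 84740436, plus strand) was present in every library, with 128 to 184 reads each. Its level was 1.89 ± 0.285 FPKM in WT and 1.6 ± 0.216 FPKM in the libraries labelled knockout (SD, n = 3 each). The log2 fold change was -0.19 with a standard error of 0.13 and a 95% interval from -0.49 to 0.11 (limma, Benjamini-Hochberg adjusted p = 0.999). WT replicate 2, at 1.57 FPKM, lay below the library labelled knockout replicate 2, at 1.84 FPKM. Without WT replicate 2 the log2 fold change was -0.29. The RNA level therefore does not check the genotype labels, and every direction below is between libraries as labelled. A noncoding gene on the other strand, D030046N08Rik, shares 1338 exon bases with Fam69c in GENCODE M21, more than the deposited Fam69c position allows. The sources used here do not state that counting used strand, so reads of the 2 genes may not be separated where they overlap. The relatives Fam69a and Fam69b gave log2 fold changes of -0.15 and -0.08, and the family list of 3 measured members did not pass the set test (camera adjusted p = 0.0937). Within 5 Mb of Fam69c, 33 genes were measured and 0 passed in limma, with 0 at an unadjusted p under 0.05.

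**Figure D1:**
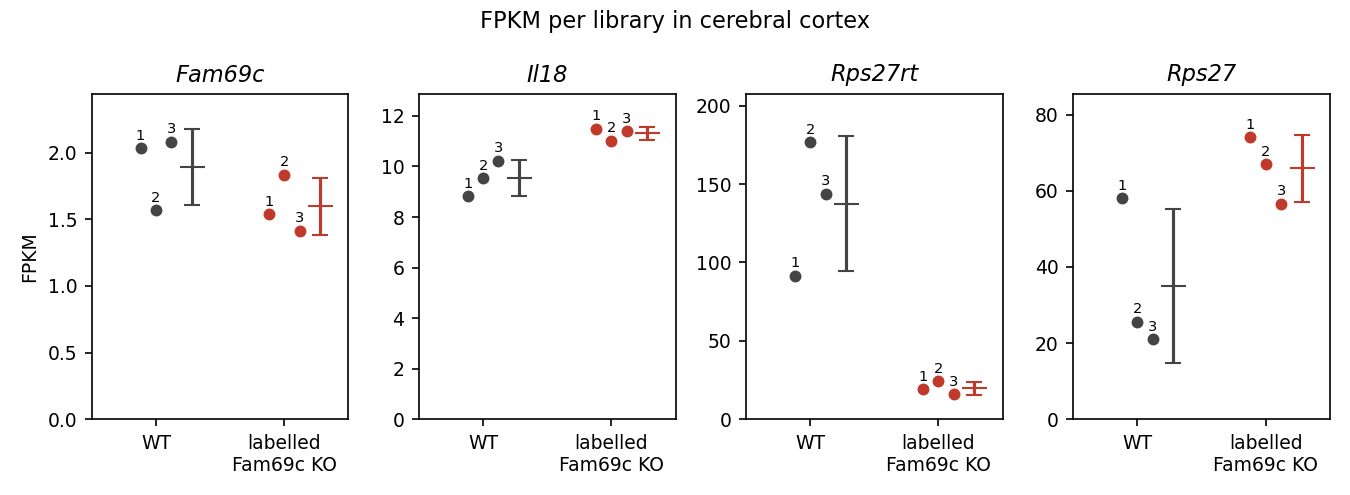
FPKM of Fam69c, Il18, Rps27rt and Rps27 in each library, WT in grey and libraries labelled Fam69c knockout in red, with replicate numbers at the points and the mean with its SD (n = 3) beside them. Fam69c overlaps between the groups, Il18 and Rps27rt do not, and Rps27 in WT replicate 1 lies within the range of the libraries labelled knockout.

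Across the transcriptome the smallest p belonged to Rps27rt, a single-exon copy of the ribosomal protein gene Rps27. Rps27rt (mm10 chromosome 9, 114982366 to 114982739) read 137 ± 43.0 FPKM in WT and 19.7 ± 4.23 FPKM in the libraries labelled knockout, a log2 fold change of -2.74 with a standard error of 0.25 (limma adjusted p = 0.228). Rps27 itself (chromosome 3, 90212522 to 90213651) read 34.9 ± 20.3 and 65.9 ± 8.78 FPKM with overlapping groups, a log2 fold change of 1.04 (limma adjusted p = 0.999). The transcripts of the pair are identical over 341 aligned bases, so the division of reads between them is uncertain.

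Of 15694 genes tested with limma, 0 passed an adjusted p of 0.05 and 599 (3.82%) had an unadjusted p under 0.05, where 784.7 would come by chance. Of these 599, 256 were higher and 343 lower in the libraries labelled knockout. With voom, also from limma, on the recovered reads, 1 gene passed, Rps27rt, with 646 at an unadjusted p under 0.05. The groups did not overlap for 1392 genes (8.87%), where chance gives 10%. The median 95% interval reached 0.21 log2 units to either side of a gene's estimate. The unadjusted count was 426, 525 and 1024 without WT replicates 1, 2 and 3, 908, 429 and 530 without replicates 1, 2 and 3 labelled knockout, and 1420 with sample weights.

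Since 0 genes passed, the 6 genes with the smallest p in each direction are given, none of which passed. Ly6a, a surface antigen of vascular and stem cells (chromosome 15, 74994877 to 74998031), read 11.5 ± 0.285 FPKM in WT and 16.5 ± 1.73 FPKM in the libraries labelled knockout, a log2 fold change of 0.50. Ccnd1, encoding cyclin D1 (chromosome 7, 144929931 to 144939925), gave a log2 fold change of 0.37, and Rgcc, a regulator of the cell cycle (chromosome 14, 79288756 to 79301645), 0.29. The histone gene Hist1h4k gave 0.47 from at most 26 reads per library. On the lower side, Igfbp2, an insulin-like growth factor binding protein (chromosome 1, 72824503 to 72852474), read 21.8 ± 1.00 and 16.9 ± 1.08 FPKM, a log2 fold change of -0.36. Gm5857, a processed pseudogene with 28 to 59 reads per library, gave a log2 fold change of -0.73. Fbxw23, a transcribed unprocessed pseudogene with 37 to 90 reads per library, gave -0.69. Mir6392 gave -0.86 from at most 20 reads per library. The other 3 were short RNA models with at most 5 reads in any library: Gm24187, Mir487b and Gm25220. Adjusted p was 0.553 for Gm24187 and Gm5857 and 0.999 for the others apart from Rps27rt (limma, n = 3 per group).

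The gene groups were 39 lists fixed before the data were examined, holding 485 measured members. By camera with a preset correlation, 5 lists passed, 2 higher and 3 lower in the libraries labelled knockout. With an estimated correlation 0 of the 5 held, each at adjusted p = 0.814 with an estimated correlation. By fry 0 lists passed, with a smallest adjusted p of 0.835. Another 13 lists passed camera under some other setting, named with each list below, where the pair means WT replicate 3 and replicate 1 labelled knockout left out together. Over all genes tested 0 members passed in limma, and 4 members in 4 lists passed adjusted over the list alone: Il18, Fgfr3, Plin4 and Igfbp2. Of 23 other settings, Plin4 and Igfbp2 passed in this way under 23 each, Fgfr3 under 13 and Il18 under 11. An exact permutation test of 3 against 3 libraries cannot go below p = 0.1, and 3 lists reached that value for their mean: the Fam69 family, the glucocorticoid response and the hippocampus list.

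Among the inflammasome genes, Il18, which encodes a cytokine precursor cut by caspase-1, read 9.53 ± 0.709 FPKM in WT and 11.3 ± 0.253 FPKM in the libraries labelled knockout, with all 3 above all 3 WT (mm10 chromosome 9, 50554827 to 50581840). Its log2 fold change was 0.24 with a 95% interval from 0.09 to 0.39, and its limma adjusted p was 0.0459 adjusted over the list alone and 0.999 over all genes. Over the list alone it did not pass without WT replicate 1 (limma adjusted p = 0.179) or 2 (0.117), or without replicate 1 (0.174), 2 (0.102) or 3 (0.145) labelled knockout. Nor did it with TPM scaling (0.0801), a replicate block (0.0739), no variance trend (0.0813), no filter (0.111), voom (0.252), the gene length trend removed (0.0642), or WT replicate 3 and replicate 1 labelled knockout left out together (0.0531). Casp1, the protease of the complex, read 1.83 ± 0.462 and 1.65 ± 0.285 FPKM, with an interval of the log2 fold change from -0.51 to 0.30. Gsdmd, which encodes the pore-forming gasdermin D, read 0.877 ± 0.160 and 0.966 ± 0.114 FPKM. Casp8 read 0.495 ± 0.155 and 0.740 ± 0.110 FPKM. The sensor Nlrp3 (0.236 ± 0.0150 and 0.147 ± 0.0716 FPKM, 14 to 32 reads), the adaptor Pycard (0.494 ± 0.0991 and 0.486 ± 0.0780 FPKM) and Il1b (0.236 ± 0.0591 and 0.158 ± 0.0774 FPKM, 7 to 19 reads) lay below the expression filter. The list of 6 measured members did not pass (camera adjusted p = 0.202), and 1 member passed adjusted over the list alone against 0 over all genes.

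**Figure D2:**
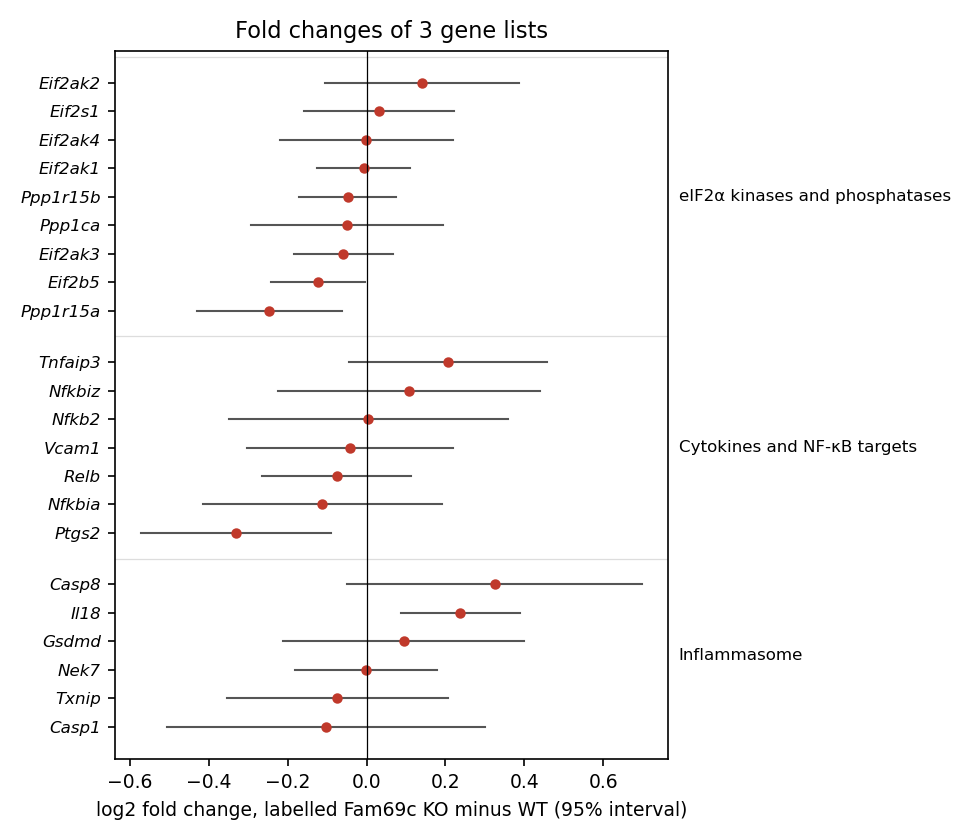
Log2 fold change of each measured member of 3 gene lists, libraries labelled Fam69c knockout minus WT, on the log2(FPKM + 0.5) scale, with bars for the 95% interval from limma (n = 3 per group). The interval of Il18 runs from 0.09 to 0.39, and that of Casp1 from -0.51 to 0.30.

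Cytokine and NF-κB target genes did not pass as a list of 7 measured members (camera adjusted p = 0.692). Ptgs2, encoding cyclooxygenase 2, read 3.69 ± 0.341 FPKM in WT and 2.83 ± 0.334 FPKM in the libraries labelled knockout, and Tnfaip3, a brake on NF-κB, 0.914 ± 0.101 and 1.13 ± 0.0846 FPKM. Lcn2, an iron-binding protein of inflamed tissue, lay below the filter, with 0.0819 ± 0.0886 FPKM in WT and 0.883 ± 0.554 FPKM in the libraries labelled knockout from 2 to 117 reads. Tnf and Il6 were covered by at most 4 and 7 reads in any library, too few to show a difference at this depth. Interferon-stimulated genes were higher for 13 of 15 members without passing (adjusted p = 0.0783), with Isg15 at 1.76 ± 0.157 and 2.17 ± 0.591 FPKM. They passed camera, higher, without WT replicate 2 (adjusted p = 0.00220), replicate 1 (0.00837) or 2 (0.0400) labelled knockout or the pair (0.0322), with no filter (0.00697), a replicate block (0.0403) and voom (0.00277). Those calls used the preset correlation. With all 6 libraries and the correlation estimated, at 0.35, the adjusted camera p was 0.814. The list did not pass camera without replicate 3 labelled knockout, which held its highest mean. Its means were -0.13, 0.06 and -0.06 log2 units in WT and -0.08, 0.03 and 0.19 labelled knockout (exact permutation p = 0.5). Antigen presentation genes (adjusted p = 0.233) included H2-K1, at 9.82 ± 0.335 and 11.7 ± 2.66 FPKM, where replicate 3 of the libraries labelled knockout held 14.7 FPKM, and passed, higher, without replicate 2 labelled knockout (0.00139). Homeostatic microglia genes (adjusted p = 0.234), disease-associated microglia genes (0.320) and complement genes (0.503) did not pass by camera. Disease-associated microglia genes passed, lower, without replicate 1 labelled knockout (0.0230) or the pair (0.0291), and complement genes, lower, without the pair (0.0322). Apoe, a lipid carrier, read 589 ± 43.8 and 522 ± 41.2 FPKM, and the microglial receptor gene Cx3cr1 9.33 ± 0.602 and 8.87 ± 0.637 FPKM. In these 6 lists 0 members passed in limma over all genes and 0 passed adjusted over the list alone.

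Stress granule components differed little between the groups. G3bp1, which nucleates the granules, read 10.4 FPKM in WT and 10.5 FPKM in the libraries labelled knockout, with an interval of the log2 fold change from -0.12 to 0.12. Its sign turned under other settings, at -0.02 with sample weights. Tia1, another granule protein, had a log2 fold change of 0.04 with an interval from -0.16 to 0.25, and Eif2s1, the initiation factor subunit whose phosphorylation slows translation, 0.03 with an interval from -0.16 to 0.22. Tia1 turned to -0.04 without the library labelled knockout replicate 2, and Eif2s1 to -0.05 without WT replicate 3. Pabpc1, the poly(A) binding protein, read 20.8 ± 0.791 and 19.0 ± 0.610 FPKM. The list of 20 did not pass (camera adjusted p = 0.594), nor did the eIF2α kinases and phosphatases (0.341). Ppp1r15a, whose product directs dephosphorylation of eIF2α, read 4.83 ± 0.273 FPKM in WT and 4.0 ± 0.332 FPKM in the libraries labelled knockout. Among integrated stress response targets (adjusted p = 0.507), the transcription factor gene Atf4 read 49.9 ± 1.6 and 44.6 ± 2.87 FPKM and Nupr1 3.61 ± 0.238 and 2.72 ± 0.290 FPKM. In these 3 lists 0 members passed in limma over all genes and 0 passed adjusted over the list alone.

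Chaperones of the endoplasmic reticulum were higher as a list, with 16 of 18 members higher in the libraries labelled knockout and a median log2 fold change of 0.07 (camera adjusted p = 0.00892, adjusted p = 0.814 with an estimated correlation). For the list mean the exact permutation p was 0.2. Replicate 2 labelled knockout, at -0.015 log2 units, lay below WT replicate 1, at -0.0076. Hspa5, the chaperone BiP, read 43.1 ± 2.53 and 47.2 ± 2.82 FPKM, and Pdia3, a disulfide isomerase, 48.0 ± 3.73 and 52.7 ± 2.02 FPKM, and 0 members passed adjusted over the list alone or over all genes. The list did not pass without WT replicate 3 (camera adjusted p = 0.124) or without replicate 3 labelled knockout (0.364), where the median was 0.03, nor with sample weights (0.179) or without both WT replicate 3 and replicate 1 labelled knockout (0.150). Cytosolic heat shock genes did not pass (adjusted p = 0.201), with the inducible Hspa1a at 3.02 ± 0.209 and 3.49 ± 0.645 FPKM. Apoptosis and p53 targets (0.897), lysosome and autophagy genes (0.594), cholesterol synthesis genes (0.156) and DNA replication genes (0.169) did not pass by camera. Heat shock genes passed, higher, without WT replicate 2 (0.0159) or replicate 2 labelled knockout (0.0333), and cholesterol synthesis genes, higher, without WT replicate 3 (0.0440) or replicates 2 (0.0400) or 3 (0.00709) labelled knockout.

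Immediate early genes, transcribed within minutes of neuronal activity, were lower as a list in the libraries labelled knockout, with 16 of 16 members lower and a median log2 fold change of -0.28 (camera adjusted p = 5.51e-05, adjusted p = 0.814 with an estimated correlation). Egr1 read 108 ± 19.9 FPKM in WT and 82.6 ± 10.6 FPKM in the libraries labelled knockout, Npas4 9.80 ± 2.02 and 7.54 ± 1.3 FPKM, and Bdnf, a neurotrophin, 4.76 ± 0.384 and 4.19 ± 0.158 FPKM. Adjusted over the list alone 0 members passed, and 0 over all genes. WT replicate 3 held the highest mean of this list, 0.47 log2 units above the mean of the 6 libraries, and without it the list did not pass, with a median of -0.09 (camera adjusted p = 0.238). The same library was lowest in striatum genes, at -0.96. The list did not pass with sample weights either (median -0.12, camera adjusted p = 0.119), nor without both WT replicate 3 and replicate 1 labelled knockout (median -0.03, 0.879). Without replicate 1 labelled knockout alone the median was -0.18. The exact permutation p of the list mean was 0.2.

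Markers of excitatory neurons (camera adjusted p = 0.692), inhibitory neurons (0.507) and synapses (0.787) did not pass. The vesicular glutamate transporter gene Slc17a7 read 305 ± 5.43 FPKM in WT and 296 ± 14.2 FPKM in the libraries labelled knockout, and the somatostatin gene Sst 245 ± 12.9 and 234 ± 25.8 FPKM. For the synapse list the median was slightly negative, -0.01, while the mean, 0.01, and the test were positive. Clock genes did not pass (adjusted p = 0.194), nor did glucocorticoid response genes (0.233), though clock genes passed, lower, without WT replicate 2 (0.0425) and the latter, lower, without WT replicate 1 (0.0405). Among glucocorticoid response genes, Plin4, a coat protein of lipid droplets, read 1.98 ± 0.327 and 0.897 ± 0.189 FPKM, a log2 fold change of -0.83, and was the 1 member that passed adjusted over the list alone (limma adjusted p = 0.00982) against 0 over all genes (0.999).

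Cytosolic ribosomal protein genes were lower as a list, with 27 of 28 members lower in the libraries labelled knockout and a median log2 fold change of -0.15 (camera adjusted p = 2.48e-08, adjusted p = 0.814 with an estimated correlation). Rps21 read 146 ± 19.7 FPKM in WT and 111 ± 17.1 FPKM in the libraries labelled knockout, Rpl13 108 ± 5.43 and 95.1 ± 5.97 FPKM, and Rps28 27.7 ± 6.52 and 19.2 ± 2.31 FPKM. These genes have many processed copies in the genome, so their counts may share reads. Nuclear genes of oxidative phosphorylation were lower for 23 of 24 members, with a median of -0.10 (camera adjusted p = 0.00108, adjusted p = 0.814 with an estimated correlation), among them Cox5b at 75.3 ± 9.59 and 62.8 ± 6.23 FPKM. Both lists had 0 members past the threshold adjusted over the list alone and 0 over all genes. The exact permutation p of the list mean was 0.2 for each, since the groups overlapped: the ribosomal list stood 0.05 log2 units above the mean of all libraries in replicate 1 labelled knockout and at -0.09 in WT replicate 3. Without WT replicate 3 the ribosomal median was -0.25. The oxidative phosphorylation median ran from -0.04 without replicate 3 labelled knockout to -0.16 without replicate 1, and was -0.06 without WT replicate 1, -0.14 without WT replicate 3 -0.06 without replicate 2 labelled knockout, -0.15 with sample weights and -0.22 without the pair. The oxidative phosphorylation list did not pass without WT replicate 1 (camera adjusted p = 0.0891), WT replicate 2 (0.0652) or replicate 3 labelled knockout (0.364). Genes of the mitochondrial genome did not pass (0.787).

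**Figure D3:**
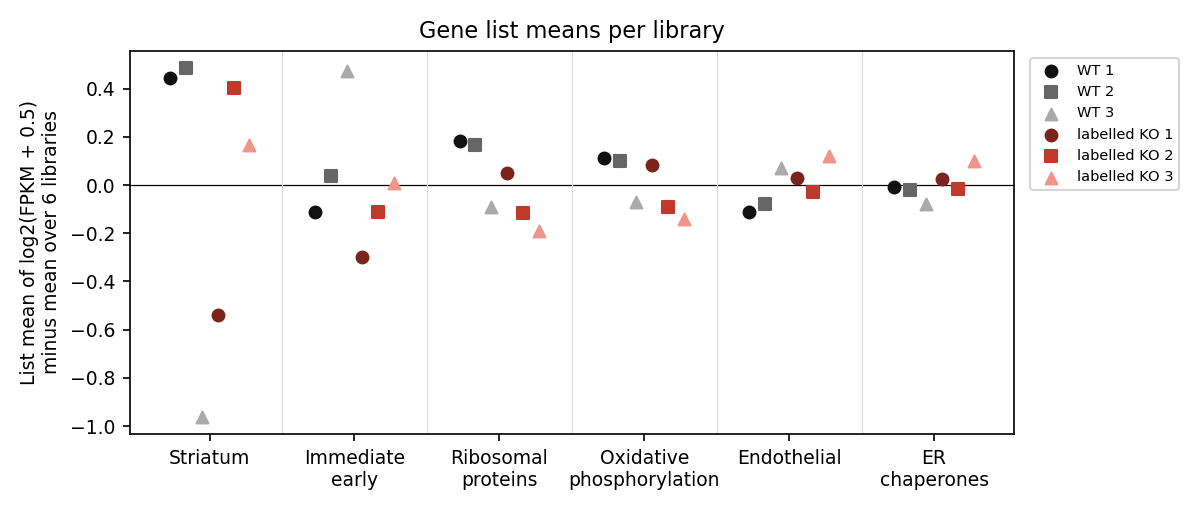
Mean of log2(FPKM + 0.5) over the members of 6 gene lists in each library, minus the mean over the 6 libraries, with WT in grey tones and libraries labelled Fam69c knockout in red tones. The striatum list is lowest in WT replicate 3, at -0.96, and in replicate 1 labelled knockout, at -0.54, and the immediate early list is highest in WT replicate 3, at 0.47.

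Endothelial genes were higher for 9 of 13 members in the libraries labelled knockout, with a median log2 fold change of 0.09 (camera adjusted p = 0.0267, adjusted p = 0.814 with an estimated correlation). For the list mean the exact permutation p was 0.3. WT replicate 3, at 0.07 log2 units, lay above replicates 1 and 2 labelled knockout, at 0.03 and -0.03. Tek, an angiopoietin receptor, read 2.01 ± 0.335 and 2.45 ± 0.358 FPKM, while the glucose transporter gene Slc2a1 read 25.3 ± 2.62 and 22.6 ± 1.70 FPKM, and 0 members passed adjusted over the list alone or over all genes. The list did not pass without WT replicate 1 (camera adjusted p = 0.340), WT replicate 2 (0.126), or replicates 1 (0.0691) or 3 (0.395) labelled knockout, nor with a filter of mean FPKM of at least 1 (0.0505) or with TPM scaling (0.0648). Pericyte and smooth muscle genes (0.430) did not pass, nor did fibroblast genes of the meninges (0.156), where Igfbp2 passed adjusted over the list alone (limma adjusted p = 0.00851) but not over all genes. The fibroblast list passed camera, lower, without replicate 1 labelled knockout (adjusted p = 0.0180), with a filter of mean FPKM of at least 1 (0.0211) and with voom (0.0227).

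Among astrocyte genes (camera adjusted p = 0.692), Fgfr3, a fibroblast growth factor receptor, read 20.8 ± 1.17 FPKM in WT and 17.5 ± 0.598 FPKM in the libraries labelled knockout and passed adjusted over the list alone (limma adjusted p = 0.0472) but not over all genes (0.999). Over the list alone it did not pass without WT replicate 1 (0.0896) or 3 (0.123), or without replicate 2 (0.0963) or 3 (0.193) labelled knockout. It also did not with TMM (0.0519), quantile (0.0576) or TPM scaling (0.0752), a replicate block (0.0526), no variance trend (0.113), or WT replicate 3 and replicate 1 labelled knockout left out together (0.0532). Aldh1l1, an astrocyte enzyme, read 11.9 ± 0.741 and 14.0 ± 1.06 FPKM. Reactive astrocyte genes (0.692) included Gfap, at 36.6 ± 1.96 and 31.7 ± 3.0 FPKM. Oligodendrocyte and myelin genes were higher for 12 of 15 members without passing (camera adjusted p = 0.0853), and precursor genes did not pass (0.515). The myelin list passed, higher, without WT replicate 2 (7.15e-05), replicates 2 (0.00337) or 3 (0.0187) labelled knockout, with quantile normalization (0.0228) and with voom (0.0227). Without the pair the myelin list passed in the other direction, lower, with a median of -0.12 (0.0322), and precursor genes passed, lower, with -0.11 (0.0322). All these calls used the preset correlation. With all 6 libraries and the correlation of the myelin list estimated, at 0.89, its adjusted camera p was 0.814.

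Genes of the striatum, which lies under the cortex, varied widely within both groups and had a mean 0.44 and 0.49 log2 units above the average in WT replicates 1 and 2 and -0.96 in WT replicate 3, against -0.54, 0.40 and 0.17 in the libraries labelled knockout (camera adjusted p = 0.885). The list passed, lower, without WT replicate 3 (0.000727) and without the pair (0.0134). Both calls used the preset correlation of 0.01. With all 6 libraries and the correlation estimated, at 0.99, the adjusted camera p was 0.947. Penk, encoding enkephalin, read 49.8 FPKM in WT replicate 3 and 150 FPKM in WT replicate 2. Ttr, which encodes transthyretin and is abundant in the choroid plexus, read 2.67 ± 0.512 FPKM in WT and 6.66 ± 2.81 FPKM in the libraries labelled knockout, all 3 above all 3 WT, without passing adjusted over the list alone (limma adjusted p = 0.0606) or over all genes. Its list did not pass (0.896), with a median of -0.00 against a positive mean, 0.13. The hippocampus list, with means of 0.08, 0.00 and 0.11 log2 units in WT and -0.04, -0.04 and -0.11 in the libraries labelled knockout, did not pass by camera (0.286). Thalamus and olfactory bulb genes (0.945) and blood genes (0.437) did not pass by camera, but blood genes passed, lower, without replicate 1 labelled knockout (0.0180) or the pair (0.0322); for the thalamus and olfactory bulb list the median and mean, both -0.02, were negative and the test positive. Y-linked genes such as Ddx3y, at 9.09 ± 0.576 and 8.58 ± 0.645 FPKM, were present in all 6 libraries, and the sex-linked list did not pass (0.589).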

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

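The voom, striatum covariate, paired removal, 200-base and gene length settings were chosen after the data were seen. The count of 0 genes held under 22 settings, leave-one-out included (0 to 0), with 599 genes at an unadjusted p under 0.05 in limma. It was 1 with voom (Rps27rt, adjusted p = 0.0374), 1 when WT replicate 3 and replicate 1 labelled knockout were left out together (Gm47283, adjusted p = 0.0337, 2095 at an unadjusted p under 0.05), and 24 at an unadjusted p under 0.05 with a log2 change of at least 1. The Fam69c log2 fold change ran from -0.29, without WT replicate 2, to -0.11, with sample weights, and was -0.11 without the pair. The count of 5 lists was 3 with sample weights, 8 with voom, 10 without that pair, 0 with an estimated correlation, 0 by fry and from 4 to 10 without single libraries, with 8 without replicate 1 and 10 without replicate 2 labelled knockout. The ribosomal list passed camera under 23 of 23 settings with a preset correlation and under 0 of 2 without one; its median of -0.15 was -0.25 without WT replicate 3, -0.23 with sample weights, -0.11 without replicate 3 labelled knockout and -0.29 without the pair. Of 402 values of 19 named genes, 390 kept their direction and side of the threshold, and 1 newly passed, Rps27rt with voom. The 11 others changed sign, all in Casp1, G3bp1, Tia1 and Eif2s1. These counts do not measure stability. They include the 6 genes per direction chosen for the smallest p in these data, and some settings, such as the replicate block, leave the fold change as it is. Without single libraries the log2 fold change ranged from -0.251 to 0.039 for Casp1 (positive without WT replicate 3), from -0.017 to 0.025 for G3bp1, from -0.038 to 0.096 for Tia1 (negative without replicate 2 labelled knockout) and from -0.047 to 0.098 for Eif2s1 (negative without WT replicate 3). With sample weights G3bp1 was -0.020 and Eif2s1 -0.015, and without the pair they were -0.0076 and -0.059. The stress granule list median ranged from -0.028 to -0.0032 without single libraries, the test turning positive without replicate 1 labelled knockout, and was 0.0085 without the pair, where the test was positive, and 0.0095 with TPM scaling, where it stayed negative. The causes of these changes were not tested.

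Deviations of same-numbered libraries correlated at 0.08, 0.01 and 0.21, against -0.16 to 0.11 for libraries with different numbers. The bound of a correlation over 0.1 in every same-numbered pair was not met, which does not exclude pairing by replicate number. WT replicates 1 and 3 correlated best with their own number and WT replicate 2 with replicate 1 labelled knockout, at 0.11. With the replicate number as a block, limma called 0 genes, 837 had an unadjusted p under 0.05, camera called 6 lists, the 1 gained being interferon-stimulated genes, and the Fam69c log2 fold change was -0.19. Apart from voom on the recovered reads, count tests were not run, since the table as deposited held no counts. Genes such as Nlrp3 and Il1b, with at most 32 and 19 reads per library, are limited by depth.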

Other observations

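The tests of swapped libraries, of an allele that keeps its RNA and of unshared overlap bases were chosen after the results were seen. So were those of the Rps27 pair and of correlated ribosomal genes. For the other tests the bounds were set before their own results. The gene length test and the test of every library labelled knockout concern the lower ribosomal list, which was itself a result of these data. Some genes varied widely inside both groups. Gapdh, a glycolytic enzyme gene with many processed copies in the genome, read 2.66, 24.6 and 3.66 FPKM in WT and 2.28, 2.67 and 39.2 FPKM in the libraries labelled knockout. The dopamine receptor gene Drd2, itself a member of the striatum list, and Lrrc10b, which is not, were lowest in the libraries lowest in that list. Drd2 ran from 4.77 FPKM in WT replicate 3 to 20.2 FPKM in WT replicate 2. Ccl21b, a chemokine gene with near-identical copies, read 0.239 FPKM in WT replicate 1 and 10.4 FPKM in replicate 1 labelled knockout. Lcn2 read 1.05, 1.34 and 0.266 FPKM in the libraries labelled knockout and at most 0.184 FPKM in WT, and Ccl6, a chemokine gene of myeloid cells, 0.649 ± 0.0778 FPKM in WT and 0.311 ± 0.108 FPKM in the libraries labelled knockout (n = 3 each), both below the filter.

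Fam69c RNA in the libraries labelled knockout stood at 84.3% of WT. The lowest of the 6 libraries held 83.2% of the median, so an exchange of libraries between groups with an allele that removes the transcript would need another source of these reads. D030046N08Rik, on the other strand, could supply 19.5% of the Fam69c reads at its own FPKM, under the bound set beforehand. With its own reads counted only on its 232 unshared bases of 1570, it could supply 132%. Both figures take 1338 shared bases from GENCODE M21 exons, which does not match the deposited Fam69c model. That model starts at 84720019, and D030046N08Rik ends at 84720775 in M21, so fewer bases can be shared. Both percentages would then be too high for the deposited model. Values for that model were not computed, so these figures do not settle the overlap. An allele that changes the protein and leaves most of the RNA, overlap reads, exchanged libraries and libraries without the knockout cannot be told apart here, since no values per exon were analysed.

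Rps27rt was lower and Rps27 higher in the libraries labelled knockout, and the summed reads of the pair differed by -0.21 log2 units (exact permutation p = 0.3, n = 3 per group) against -2.74 for Rps27rt alone. Less Rps27rt RNA with no change of Rps27 has values against it but stays open. The limma interval of Rps27 lay above 0, with a lower bound of 0.21. Its unadjusted limma p was above 0.05 without WT replicate 2 (0.067) or 3 (0.062), or replicate 1 (0.065) or 2 (0.054) labelled knockout. That p was 3.9e-05 without WT replicate 1 and 0.033 without replicate 3 labelled knockout. Without WT replicate 3 and replicate 1 labelled knockout together it was 0.143. The sum lay 0.89 log2 units above the level expected with Rps27 as in WT. From the libraries' own spread the 95% interval of that difference ran from -0.57 to 2.35 (exact permutation p = 0.2), since the lowest sum labelled knockout minus the level expected from WT replicate 1 was -0.07 log2 units; without WT replicate 1 the difference was 1.26. A different division of reads between near-identical copies may account for the contrast, and the share of the pair's reads given to Rps27rt was 36.1%, 71.2% and 71.1% in WT and 8.43%, 11.5% and 9.11% in the libraries labelled knockout, a range of 62.8 percentage points. A sequence variant between the mice that moves reads could give such levels, but so could any other cause of the division, and no reads were analysed.

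Ribosomal protein genes were lower as a list in the libraries labelled knockout. A gene length trend as the whole cause is argued against by the median log2 fold change of the list. That median was -0.15 in the main test and -0.14 with the trend removed. The adjusted camera p without the trend, 8.57e-09, used the preset correlation, so it is not weighed here. Members that move together between libraries whatever the group stay open: with the correlation estimated at 0.79 the adjusted p was 0.814, but the difference between groups, -0.17, was smaller in size than the ranges within groups (0.27 in WT, 0.24 labelled knockout) and larger than their SDs (0.15 and 0.12). List means were 0.18, 0.17 and -0.09 log2 units in WT and 0.05, -0.12 and -0.19 labelled knockout. WT replicates 1 and 2 and replicate 1 labelled knockout thus lay above the rest, across the groups. Oxidative phosphorylation means divided likewise, at 0.11, 0.10 and -0.07 in WT and 0.08, -0.09 and -0.14 labelled knockout. This same split gave 2778 genes at an unadjusted limma p under 0.05. The cause of this division was not tested. Lower ribosomal protein mRNA in every library labelled knockout stays open too. The highest of their list means lay 0.14 log2 units above the lowest WT mean, which by the bound set beforehand goes against it. That gap rests on 1 library in each group and lies within the WT SD, though beyond the other. An effect of genotype in part of the libraries stays open, as untested.

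The 6 libraries make 10 splits into groups of 3, too few for a share under 0.05. The real split gave 0 genes, so all 10 splits gave as many, and the highest other gave 1. For the lists the real split gave 5, 8 of the 10 splits gave as many, and the highest other gave 10. Over the 10 splits the genes at an unadjusted p under 0.05 ran from 306 to 2778, with 599 for the real split. The split with 2778, WT replicates 1 and 2 and replicate 1 labelled knockout against the rest, was picked after the counts were seen, and no value for the highest of 10 splits without structure was computed.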
